A study of Mus musculus with 7 samples.

How the data were processed

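RNA sequencing of isolated mouse hepatocytes, the main parenchymal cells of the liver, was analysed in 7 libraries, 3 wild-type (WT) and 4 ALAS1/2-KO. Groups and replicate numbers came from the sample titles and the genotype labels. Per the labels' protocols, RNA was taken up in Trizol, 1 µg of total RNA went into each library, and libraries were made with the TruSeq RNA kit, version 2. Per the submitters' processing notes, the tools were cutadapt, which trims adapters, and HISAT2, a spliced aligner, with the mouse build mm10. Versions, the read counter, the gene annotation, strand handling and the software behind the final values are not given in the sources used here. Reads that fit several near-identical genes may have been split or dropped, so values of gene families such as Cyp, Ugt, Ces, Mup, Ly6 and hemoglobin are uncertain at the level of single members. The same holds for mitochondrial genes with a copy in the nuclear genome and for genes that overlap a neighbour.

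The authors deposited a table named as CPM, but the values are on a log2 scale: log2 CPM (counts scaled to library size) with a small prior, for 12151 gene symbols in 7 columns. 2 to the power of each value, minus a floor of 0.0676 CPM common to all columns, was a whole multiple of a fixed step in each column for 100% of values, within 0.01 reads. The steps gave the reads per gene, and their sum gave the depth of each library. The library sizes behind the deposited values had been scaled, to 0.801 to 1.003 times the listed reads in WT and 1.069 to 1.184 times in ALAS1/2-KO. Every listed gene reached 0.5 CPM in 3 or more libraries, so genes below that level were not analysed here. CPM values below are the deposited values taken off the log2 scale, with the floor subtracted.

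The design set before the data were examined assumed CPM and log2(CPM + 1). Because the table already held log2 values, the test was run on these as deposited, and a pseudocount of 1 was added as an alternative. Genes with at least 1 CPM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance moderation. P-values were two-sided with Benjamini-Hochberg adjustment over the 12105 genes tested, and an adjusted p under 0.05 counted as changed. Fold changes are ALAS1/2-KO over WT. They include the deposited prior, which understates the change of genes at low CPM. Single values were compared by an exact two-sided permutation test over all 35 regroupings of the libraries, which cannot give a p below 0.0286.

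Gene lists for liver pathways, and markers of other cell types that a hepatocyte preparation could hold, were fixed before the data were examined. The 39 lists with at least 5 tested members were tested with camera in limma with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in the same direction, were the alternatives. For 15 microRNA seed families, 12 abundant in liver and 3 controls from other tissues, genes with an 8mer site in the longest annotated 3' UTR were compared with genes without a site, matched on deciles of UTR length and expression. Sites, positions and identifiers came from the GENCODE M21 annotation of mm10, which matched 11938 symbols to a single gene. The seed test covered 11218 genes with an annotated 3' UTR. A microRNA pairs with its targets through such seed sites, and loss of its activity would raise them.

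Genes named in the text follow a rule fixed beforehand. It takes Alas1 and Alas2, then the 12 largest increases and 12 largest decreases among changed genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out pseudogenes and unnamed gene models. From each list it takes up to 4 changed members with the smallest p, or the 2 most abundant members where none changed. Alternatives were other pseudocounts, other filters, other library scalings, limma without trend, limma array weights, a replicate block, and leaving out each library. Chosen after seeing the data were the pseudocount of 1, CPM rescaled to listed reads, limma voom on the recovered reads, a non-parenchymal marker score as covariate, and leaving out ALAS1/2-KO replicates 1 and 2 together. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

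The procedure was tested on simulated data, in which 200 genes were changed by known amounts in libraries of the real depth. The spread of each gene was taken from the real libraries, capped for the most variable genes, and counting noise was added to it. Of 11969 genes tested there, 10.2% of those changed by 0.5 on the log2 scale were recovered, 74% at 1, 94% at 2 and 96% at 3, and 13 of 11731 unchanged genes were called. A list of 39 genes shifted by 0.5 was called with the preset correlation and with the estimated correlation, and 0 of the 38 other lists were called. The simulated genes varied independently of each other, whereas the correlation estimated in the real lists reached 0.962, for endothelial markers. The simulation therefore does not show how often lists are wrongly called in the real data. A seed family shifted by 0.2 in the simulated libraries was recovered at 0.189 over 11100 genes. Its exact p of 0.0286 became 0.2857 after adjustment over the 15 families, because at least 9 families would have to reach the smallest p together for any to pass. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.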

Results

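Messenger RNA was profiled in hepatocytes isolated from mouse liver, in 3 wild-type (WT) libraries and 4 libraries labelled ALAS1/2-KO. ALAS1 and ALAS2 are the aminolevulinic acid synthases, which catalyse the entry step of heme synthesis. ALAS1 acts in most tissues and ALAS2 in red cell precursors. In the ALAS1/2-KO group, exons 4 and 5 of Alas1 were to be deleted by an inducible Cre and Alas2 was to be lowered with a small interfering RNA coupled to GalNAc, a sugar taken up by hepatocytes. These libraries carry a tamoxifen label and the WT libraries carry none, so genotype, tamoxifen and siRNA cannot be told apart. The series addresses a role of ALAS1 outside heme synthesis, in silencing by small RNAs. Recovered reads per library ran from 22916097 to 34048680 in WT and from 27933939 to 30195635 in ALAS1/2-KO, and 1 read was worth 0.0293 to 0.0522 CPM.

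Alas2 was nearly lost in the ALAS1/2-KO libraries and Alas1 transcripts were not. Alas2 (ENSMUSG00000025270.13, chromosome X, 150547375 to 150570638, mm10, plus strand) stood at 11.3 ± 5.18 CPM in WT (SD, n = 3) and 0.44 ± 0.26 CPM in ALAS1/2-KO (SD, n = 4). It fell 22.8-fold in limma (log2 fold change -4.51, SE 0.46, adjusted p = 0.0027), lower in each of the 4 libraries than in any WT library (exact p = 0.0286, the smallest the design allows). Alas1 (ENSMUSG00000032786.16, chromosome 9, 106233455 to 106248654, minus strand) stood at 209 ± 109 CPM in WT and 322 ± 31.7 CPM in ALAS1/2-KO. The Alas1 difference did not pass the limma threshold (log2 fold change 0.80, SE 0.41, adjusted p = 0.277), although each ALAS1/2-KO library lay above each WT library (exact p = 0.0286). WT replicate 3, at 83.5 CPM, set much of it, and without that library the log2 fold change was 0.24. Exons 4 and 5 make up 373 of the 3089 nt, or 12.1%, of the Alas1 transcript with 11 exons. A value for the whole gene therefore does not check their deletion, and of the alternatives run the Alas1 log2 fold change passed the threshold only with CPM rescaled to listed reads (1.14, adjusted p = 0.0432, against 0.249 to 0.484 in the others).

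**Figure D1:**
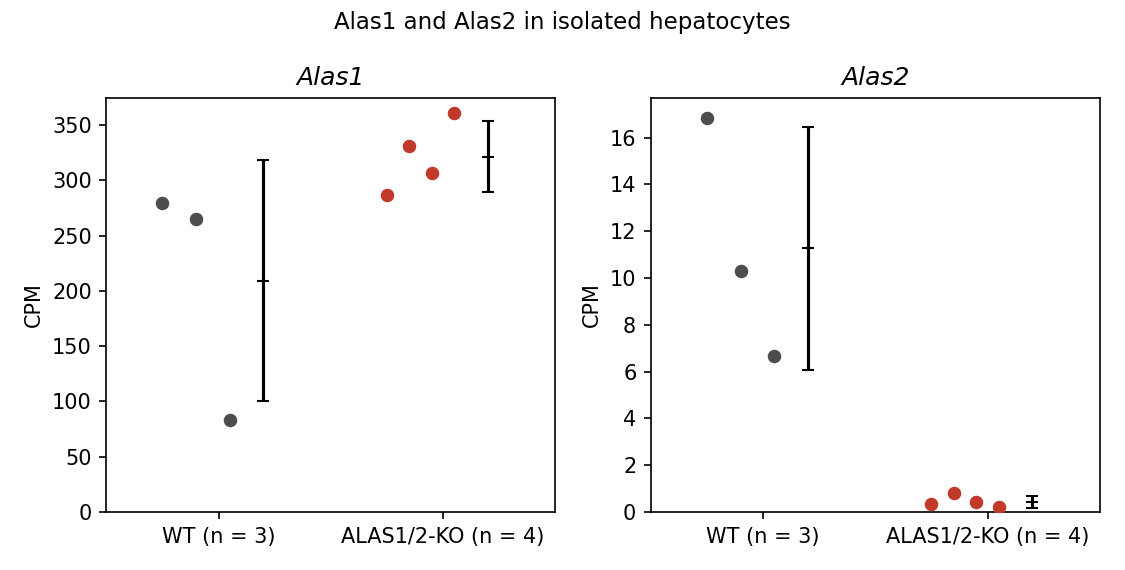
CPM of Alas1 and Alas2 in each library (points), with the group mean and SD beside them (bars), for 3 WT and 4 ALAS1/2-KO libraries. Alas2 averages 0.44 CPM in ALAS1/2-KO against 11.3 in WT, and the WT point far below the rest for Alas1 is replicate 3, at 83.5 CPM.

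Across the transcriptome, the most strongly raised genes included lipid and drug metabolism enzymes, and the most strongly lowered ones were of mixed function. Scd1, the desaturase that makes monounsaturated fatty acids, rose 8.9-fold from 423 ± 177 to 3602 ± 595 CPM (SD, n = 3 and 4, limma adjusted p = 0.00119). Cyp2b10, a drug-metabolizing cytochrome P450 and classical target of the nuclear receptor CAR, rose 8.74-fold from 11.1 ± 2.59 to 96.9 ± 13.6 CPM (limma adjusted p = 0.000114). Dsg1c, a desmosomal cadherin, fell 25-fold from 36.6 ± 1.01 to 1.45 ± 0.41 CPM (limma adjusted p = 9.52e-05). Ugt2b1, a glucuronosyltransferase, fell 8.99-fold from 350 ± 20.7 to 40.9 ± 14.5 CPM (limma adjusted p = 0.00154).

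In limma, 617 of 12105 genes changed, 352 higher and 265 lower, and 267 of them (110 higher, 157 lower) by at least 1 on the log2 scale. All 617 had no overlap between the groups, as did 2745 of all genes tested, or 22.7% where chance gives 5.7%. An unadjusted limma p under 0.05 was reached by 2869 of the 12105 genes, where chance gives 605. Counts at that level within a list, given below, are to be read against this share. Of the 12 largest increases, Plch2 (3.76), a phospholipase C, Cyp4a12b (3.41), Scd1 (3.15), Cyp2b10 (3.13), Ly6a (2.80), Adam11 (2.71), Eppk1 (2.43), Cyp2c55 (2.21), Cyp8b1 (2.17), Chrna4 (2.16), Itih5 (2.15) and Cyp3a59 (2.07) are given with their log2 fold changes. The 12 largest decreases were Dsg1c (-4.64), Alas2 (-4.51), Corin (-4.32), a membrane protease, Krt4 (-4.31), Myo15b (-3.85), Hsd3b5 (-3.76), Tsen54 (-3.66), Obp2a (-3.21), Ugt2b1 (-3.17), Ptgds (-3.12), Slc22a28 (-3.08) and Slc34a2 (-2.92). Among the 86 named genes that changed, 37 passed in each of the 7 fits without a library, including Scd1, Cyp2b10, Dsg1c, Ugt2b1 and Alas2. Of the other 49, 48 lost the call without WT replicate 2, 32 without WT replicate 1, 28 without WT replicate 3, and 2, 20, 21 and 34 without ALAS1/2-KO replicates 1, 2, 3 and 4. Among the 24 largest changes these were Hsd3b5, Cyp3a59, Chrna4 and Slc34a2 (adjusted p = 0.128, 0.123, 0.141 and 0.153 without WT replicate 2). The count was 231, 100 and 331 without WT replicates 1, 2 and 3, and 379, 338 and 210 without ALAS1/2-KO replicates 2, 3 and 4. Without ALAS1/2-KO replicate 1 it was 802, and without ALAS1/2-KO replicates 1 and 2 together 1130. The share of higher calls was 57.1%, against 43.4% when libraries were scaled without the 20 most abundant and the mitochondrial genes. With CPM rescaled to listed reads it was 92.6%, because the median of all genes then moved from -0.02 to 0.32.

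Tsen54, a subunit of the tRNA splicing endonuclease, and Myo15b, a myosin, lie close together on chromosome 11 (115814724 to 115823094 and 115858406 to 115892603). Tsen54 fell from 53.7 ± 11.5 to 4.16 ± 0.68 CPM and Myo15b from 10.1 ± 1.39 to 0.66 ± 0.26 CPM. Caskin2, next to Tsen54 and chosen after its values were seen, also fell, from 43.5 to 13.9 CPM (log2 fold change -1.63, limma adjusted p = 0.000743). Llgl2, between Tsen54 and Myo15b, stood at 13.1 CPM in WT and 12.5 in ALAS1/2-KO and did not pass (log2 fold change -0.08, limma adjusted p = 0.821). Ptgds and Obp2a, both among the 12 largest decreases, also lie near each other, on chromosome 2 (25466709 to 25470046 and 25700043 to 25703326). Ly6a and Eppk1, both among the 12 largest increases, start at 74994877 and 76101481 on chromosome 15. Whether the groups share a strain background, at these loci or elsewhere, is not given in the sources used here, and a strain difference was not tested.

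**Figure D2:**
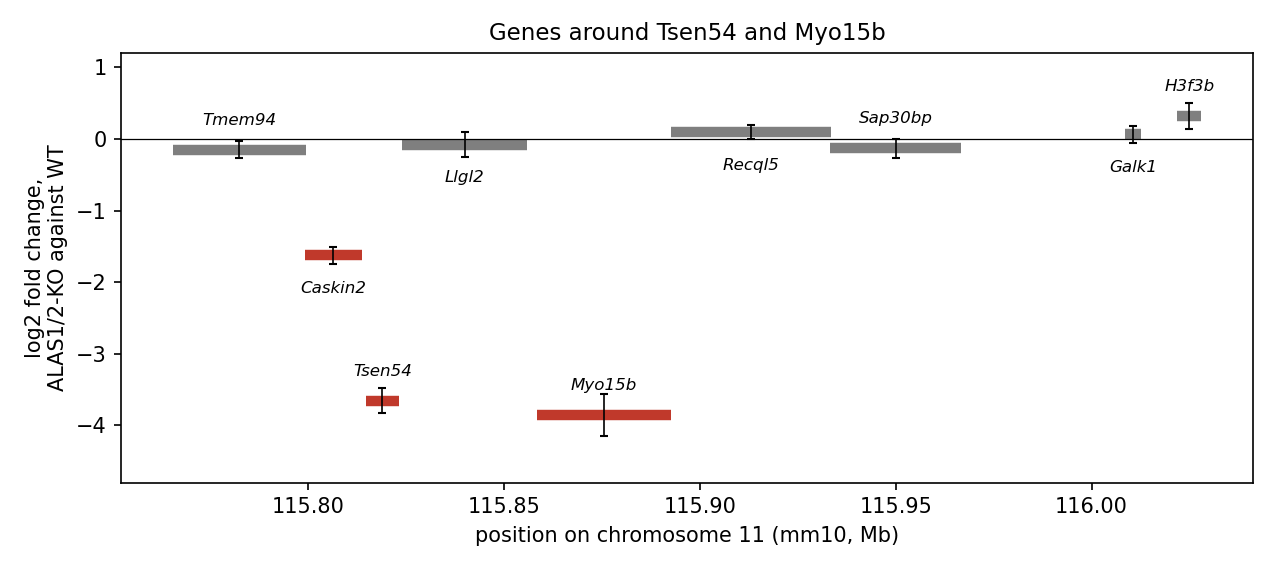
Log2 fold change (bars, ± SE) of the genes measured around Tsen54 and Myo15b against their position on chromosome 11 of mm10, with changed genes in red. Caskin2, Tsen54 and Myo15b lie at -1.63, -3.66 and -3.85, and Llgl2 between the last 2 lies at -0.08.

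Several genes of fatty acid and triglyceride synthesis rose. Of 23 tested, 10 rose and 0 fell (14 and 1 adjusted over the list alone, the 1 being Cd36, a fatty acid transporter, chosen after its values were seen, at 39.8 and 19.8 CPM), with Elovl6 2.94-fold, Acly 2.44-fold and Fads2 2.16-fold higher beside Scd1. The list passed camera (median log2 fold change 0.68, adjusted p = 1.19e-08, and adjusted p = 0.474 with an estimated correlation) and fry (adjusted p = 0.015). In glycolysis and gluconeogenesis 6 of 26 rose and 0 fell (8 and 1 adjusted over the list alone), among them Pklr, liver pyruvate kinase, 2.8-fold, Slc2a2, the hepatocyte glucose transporter, 2.1-fold, and Gys2 and Gapdh. That list did not pass camera (adjusted p = 0.051), but did without WT replicate 1 (0.000648), WT replicate 2 (0.0319) or ALAS1/2-KO replicate 2 (0.0217). With all libraries kept, it passed with scaling without the 20 most abundant and mitochondrial genes (0.0238) and with limma voom (0.0399). Cholesterol synthesis had 2 of 24 higher (4 higher and 1 lower adjusted over the list alone), among them Mvd 1.55-fold, with a camera adjusted p = 0.0358, and adjusted p = 0.654 with an estimated correlation. Of 27 genes of fatty acid oxidation and ketogenesis, Ppara, Acaa1b and Creb3l3 were among 4 that rose and Ehhadh, a peroxisomal enzyme, fell 2.26-fold (8 and 3 adjusted over the list alone), with a camera adjusted p = 0.0363, and adjusted p = 0.771 with an estimated correlation. The cholesterol list lost its call without WT replicate 1 or 3 or ALAS1/2-KO replicate 1 or 2 (adjusted p = 0.175, 0.0565, 0.0965 and 0.0947), and the oxidation list without WT replicate 3 or ALAS1/2-KO replicate 1, 3 or 4 (0.0923, 0.127, 0.061 and 0.0676). Mvd, Gys2, Gapdh, Ppara, Acaa1b and Creb3l3 lost theirs without WT replicate 2 (0.118, 0.132, 0.0753, 0.12, 0.152 and 0.152), and passed in 3, 2, 1, 4, 3 and 3 of the 7 fits without a library.

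Genes of drug metabolism and bile acids included calls in both directions. Of 17 targets of the nuclear receptors CAR and PXR, 8 rose and 4 fell (10 and 4 adjusted over the list alone). Cyp2b10, Cyp2c55, Ces2a (3.47-fold) and Gstm3 (3.14-fold) led, with a median log2 fold change of 0.78. Camera gave an adjusted p = 0.000398, and adjusted p = 0.474 with an estimated correlation, and fry an adjusted p = 0.00955. With CPM rescaled to listed reads, camera gave an adjusted p = 0.0536 for this list. Across 35 cytochromes P450 of families 1 to 3, heme enzymes of drug metabolism, 6 rose and 4 fell (11 and 9 adjusted over the list alone), with Cyp2f2 2.96-fold, Cyp2c23 1.71-fold and Cyp3a13 1.59-fold higher. The list had a median of 0.03 and a mean of -0.11 and did not pass (camera adjusted p = 0.434, upward). In the list of other heme proteins, which also holds Por, 2 of 30 rose and 2 fell (3 and 5 adjusted over the list alone). Por, the electron donor of these enzymes, rose 2.92-fold and Cyp8b1, a bile acid hydroxylase, 4.51-fold, while Cyp17a1 fell 5.72-fold and Cyp7b1 5-fold (camera adjusted p = 0.382). This list passed with quantile normalization (0.0453) and with the non-parenchymal score as covariate (0.0231), and its mean was lower in each ALAS1/2-KO library than in any WT library (exact p = 0.0286, adjusted p = 0.1173, values shared by 9 other lists). In bile acid synthesis and transport, 4 of 20 rose and 2 fell (7 and 4 adjusted over the list alone). Slc10a1 and Abcc2, bile acid and conjugate transporters, rose 1.72-fold and 1.64-fold, and Akr1c6 fell 2.65-fold (camera adjusted p = 0.468, upward by test against a median of -0.10 and a mean of -0.13). NRF2 antioxidant genes had 7 of 25 higher and 1 lower (9 and 2 adjusted over the list alone), led by Gstm3, Ces2g, Ephx1 and G6pdx, with a camera adjusted p = 0.0421 upward against a median of -0.02 and a mean of 0.13, and adjusted p = 0.587 with an estimated correlation. It lost the call without WT replicate 1 or 3 or ALAS1/2-KO replicate 1 or 2 (0.0872, 0.0923, 0.0799 and 0.0862), and with quantile normalization, array weights, CPM rescaled to listed reads, no limma trend or the non-parenchymal score as covariate (0.259, 0.189, 0.0729, 0.0572 and 0.159). Without WT replicate 2, Cyp2c23, Por, Cyp7b1, Slc10a1, Abcc2, Akr1c6 and G6pdx lost theirs (limma adjusted p = 0.0695, 0.154, 0.113, 0.0533, 0.0713, 0.0543 and 0.0523). Of the 7 fits without a library, Cyp7b1 passed in 1, Por in 3 and the others in 6.

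The rest of heme synthesis showed no change that passed the test. Of the 7 enzymes after ALAS, limma called 0, with 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by limma voom, and their log2 fold changes ran from -0.24 (Alad) to 0.19 (Ppox). Fech, which inserts the iron, stood at 81.2 ± 5.92 CPM in WT and 81.2 ± 8.47 CPM in ALAS1/2-KO (SD, n = 3 and 4), and Cpox at 61.9 and 71.8. The list did not pass (camera adjusted p = 0.703). Heme breakdown, transport and sensing also had 0 of 19 called by limma, 0 adjusted over the list alone, 0 by limma voom and 5 at an unadjusted p under 0.05, with Hpx at 5703 and 4333 CPM and Hp at 5625 and 3827 (camera adjusted p = 0.468). In iron storage and transport Hamp2, a hepcidin gene, rose 3.48-fold, alone among 22 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.605). It was not called by limma voom, or without WT replicate 1 or 2 or ALAS1/2-KO replicate 4 (limma adjusted p = 0.075, 0.118 and 0.0556).

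Several interferon-stimulated genes rose. Of 28, 11 rose and 0 fell (18 and 0 adjusted over the list alone), with Usp18 2.83-fold, Rsad2 2.58-fold, Gbp3 2.32-fold and Irf7, an interferon regulatory factor, 1.96-fold higher. The median log2 fold change was 0.62 (camera adjusted p = 5.93e-11, and adjusted p = 0.474 with an estimated correlation and 0.0519 by fry). Inflammatory cytokines and chemokines had 0 of 11 called by limma and by limma voom, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (Nfkbia 55.3 and 42.8 CPM, Cxcl1 60.1 and 34.1, camera adjusted p = 0.114, and 0.0232 without WT replicate 1). That list also passed camera with the replicate block (0.0173) and with CPM rescaled to listed reads (0.00746). In the acute phase list 1 of 25 fell, Apcs, 2.93-fold (1 adjusted over the list alone, camera adjusted p = 0.207). Of 20 p53 targets, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Eda2r 2.19-fold, Ccng1 1.76-fold, Aen 1.67-fold and Mdm2 1.4-fold higher (camera adjusted p = 0.0261, and adjusted p = 0.474 with an estimated correlation). Without WT replicate 3 the p53 list did not pass (0.0923), and with CPM rescaled to listed reads it did not either (0.0809). Eda2r, Ccng1, Aen, Mdm2, Rsad2 and Gbp3 lost their calls without WT replicate 2 (limma adjusted p = 0.128, 0.0757, 0.0756, 0.118, 0.078 and 0.0523). Of the 7 fits without a library, Aen passed in 1 (0.0922 without WT replicate 1), Eda2r and Mdm2 in 2 and the others in 6.

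A few clock genes changed. Of 19, 3 rose, among them Per2 (3.33-fold) and Bhlhe40 (1.65-fold), and Nfil3 fell 1.67-fold (10 higher and 2 lower adjusted over the list alone), with a camera adjusted p = 0.000688, and adjusted p = 0.508 with an estimated correlation and 0.0705 by fry. The WT libraries were themselves spread on this list, at 0.62, -0.08 and -0.55 around their mean in replicates 1, 2 and 3, and the ALAS1/2-KO libraries lay between 0.77 and 1.06. Without WT replicate 2, Per2, Bhlhe40 and Nfil3 lost their calls (limma adjusted p = 0.154, 0.166 and 0.101), and they passed in 2, 2 and 1 of the 7 fits without a library. Of 20 male-biased liver genes 6 fell and 1 rose (9 and 2 adjusted over the list alone). Hsd3b5, a steroid dehydrogenase, fell 13.6-fold, C6 2.31-fold and Mup3 1.82-fold, while Cyp4a12b rose 10.6-fold (camera adjusted p = 0.00388, and adjusted p = 0.654 with an estimated correlation). Of 12 female-biased genes, Hamp2 rose and Cyp17a1 and Cyp3a44 fell (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.971, downward against a median of 0.42 and a mean of -0.20). Y-linked Ddx3y and Eif2s3y were present in both groups and the 4 sex chromosome genes were not called by limma or limma voom, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Without WT replicate 2, C6, Mup3 and Hsd3b5 lost their calls (limma adjusted p = 0.0704, 0.0753 and 0.128, passing in 6, 6 and 2 of the 7 fits without a library), and without WT replicate 1 or 3 Cyp3a44 did (0.0662 and 0.0563).

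The mitochondrial genome and albumin took a smaller share of the libraries in ALAS1/2-KO. Mitochondrially encoded genes made up 37.9% ± 5.68 of listed reads in WT and 23.8% ± 4.72 in ALAS1/2-KO (SD, n = 3 and 4, exact p = 0.0286). Alb took 8.62% ± 1.18 and 5.91% ± 0.52 (exact p = 0.0286). Of 13 mitochondrially encoded subunits of oxidative phosphorylation 5 fell (13 adjusted over the list alone), among them mt-Nd2 2.17-fold and mt-Co3 5.94-fold, with mt-Nd3 and mt-Nd4l (camera adjusted p = 3.45e-08, and adjusted p = 0.508 with an estimated correlation). Several of these share sequence with a nuclear copy on chromosome 1 and are uncertain. Without WT replicate 2, mt-Nd2, mt-Co3, mt-Nd3 and mt-Nd4l lost their calls (limma adjusted p = 0.18, 0.153, 0.154 and 0.178), passing in 2, 2, 2 and 3 of the 7 fits without a library. The 39 nuclear subunits had 0 called by limma and by limma voom, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05, with Atp5b at 466 and 563 CPM and Atp5a1 at 344 and 433 (camera adjusted p = 0.0646). Their list passed without WT replicate 1 or 2 or ALAS1/2-KO replicate 3 or 4 (0.00504, 0.00918, 0.0284 and 0.00303). With all libraries kept, it passed with the replicate block (0.000749) and with CPM rescaled to listed reads (0.000303). Alb fell 1.83-fold and Apoh 1.66-fold, the 2 of 27 hepatocyte identity genes that fell (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.468), and Apoh lost its call without WT replicate 2 (limma adjusted p = 0.129) and passed in 3 of the 7 fits. After quantile normalization Alb reversed to a log2 fold change of 0.28 and mt-Nd2 shrank to 0, both far from called, since the most abundant genes then receive shared values.

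The pericentral, cell cycle and dedifferentiation lists passed camera with the preset correlation, and the periportal and stress lists did not. Cyp2f2 and Pigr rose in the periportal list (2 of 18, with Alb lower, 3 and 1 adjusted over the list alone, camera adjusted p = 0.0754, and 0.00144 without WT replicate 1, 0.0491 and 0.0452 without ALAS1/2-KO replicate 3 or 4). The periportal list also passed with scaling without the 20 most abundant and mitochondrial genes (0.0164) and with the replicate block (0.0317). Of 21 pericentral genes 4 fell, including Lgr5 and Cyp2a5, each 2.55-fold, and Aldh1a1 1.96-fold, and Gstm3 rose (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0355, and adjusted p = 0.695 with an estimated correlation), a call lost without WT replicate 2 or ALAS1/2-KO replicate 2 (0.165 and 0.0862). In the cell cycle list Mcm2, a replication helicase subunit, fell 1.9-fold, the single call among 28 (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 6.83e-06, and adjusted p = 0.508 with an estimated correlation), and it passed in 0 of the 7 fits without a library. Dedifferentiation and regeneration genes had Ly6d higher and Spp1 (6.65-fold) and S100a11 lower among 15 (2 and 5 adjusted over the list alone, camera adjusted p = 0.0409, and adjusted p = 0.587 with an estimated correlation), a call lost without WT replicate 3 (0.178) and with the non-parenchymal score as covariate (0.116). It was also lost with a filter of 5 CPM, scaling without the 20 most abundant and mitochondrial genes, array weights and the replicate block (0.19, 0.0877, 0.063 and 0.0712). ALAS1/2-KO replicate 1, lowest in that score (-1.80), was also lowest in this list, at -1.13 against -0.52 to -0.41. In the integrated stress response Stbd1 alone rose, 2.52-fold, of 22 (1 adjusted over the list alone, camera adjusted p = 0.804). Stbd1, Pigr, Lgr5, Cyp2a5, Aldh1a1, Ly6d, Spp1 and S100a11 lost their calls without WT replicate 2 (limma adjusted p = 0.0875, 0.119, 0.179, 0.162, 0.178, 0.118, 0.0535 and 0.144). They passed in 5, 4, 2, 2, 1, 4, 6 and 2 of the 7 fits without a library. Endoplasmic reticulum chaperones (0 of 22, Calr 759 and 759 CPM, Hsp90b1 734 and 682, camera adjusted p = 0.98), immediate early and heat shock genes (0 of 21, Hspa8 469 and 588 CPM, Zfp36 324 and 425, camera adjusted p = 0.143) and urea cycle genes (0 of 29, Cps1 1140 and 1536 CPM, Ass1 990 and 1106, camera adjusted p = 0.407, and 0.00504 without WT replicate 1) had 0 called by limma and by limma voom. Adjusted over the list alone there were 0 in each, and 5, 2 and 6 had an unadjusted p under 0.05. The urea cycle list also passed with the replicate block (camera adjusted p = 0.0373).

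Markers of other liver cells stood lower in some ALAS1/2-KO libraries. All 16 stellate and 18 endothelial markers had negative log2 fold changes, with medians of -1.37 and -1.02, and 0 of either list was called by limma, also 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 13 stellate and 6 endothelial markers, and limma voom called 0 and 1. Dcn, a stellate transcript, stood at 141 ± 39.1 and 68.4 ± 40.6 CPM, Ecm1 at 124 and 52.9, and the endothelial Aqp1 and Fcgr2b at 88.3 and 41.9 and at 66.9 and 37.7. Without ALAS1/2-KO replicate 1 the medians were -0.96 and -0.56. Both lists passed camera (adjusted p = 2.63e-06 and 1.66e-05, and adjusted p = 0.587 and 0.654 with an estimated correlation). Extracellular matrix genes, which share cells of origin with these, had a median of -1.15 (-0.76 without ALAS1/2-KO replicate 1), with 0 of 18 called by limma and by limma voom, 0 adjusted over the list alone and 10 at an unadjusted p under 0.05 (Fn1 1843 and 1588 CPM, Sparc 96.3 and 41.4, camera adjusted p = 1.66e-05, and adjusted p = 0.587 with an estimated correlation). Kupffer cell markers had a median of -0.46 and 0 of 21 called by limma and by limma voom, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (Cd5l 267 and 274 CPM with a log2 fold change of -0.29, Clec4f 220 and 188, camera adjusted p = 0.143). The Kupffer list passed downward without ALAS1/2-KO replicate 3 or 4 (0.0106 and 0.0166). Its median was 0.08 without ALAS1/2-KO replicate 1. It passed upward without ALAS1/2-KO replicates 1 and 2 (median 0.37, adjusted p = 2.89e-05). Over the stellate, endothelial and Kupffer lists a non-parenchymal score of ALAS1/2-KO replicate 1 was -1.80 and that of replicate 2 -0.42, and the other 5 libraries lay between 0.16 and 0.70.

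Of 7 erythroid markers Hbb-bt, a hemoglobin beta chain, fell from 2.07 to 0.35 CPM (5 lower adjusted over the list alone, camera adjusted p = 0.00695, and adjusted p = 0.557 with an estimated correlation). It passed in 1 of the 7 fits without a library and was not called by limma voom. The B cell genes Ighm (2.91-fold) and Cd79a (4.55-fold) fell among 9 lymphocyte markers (2 adjusted over the list alone, camera adjusted p = 0.0409, and adjusted p = 0.747 with an estimated correlation), a call lost without WT replicate 3 or ALAS1/2-KO replicate 1 (0.192 and 0.119) and with the non-parenchymal score as covariate (0.604, median -0.22 against -0.93). Ighm and Cd79a lost theirs without WT replicate 2 (limma adjusted p = 0.101 and 0.156), each passing in 3 of the 7 fits. Of 5 neutrophil markers 0 were called by limma and by limma voom, 3 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (Lcn2 86.5 and 49.8 CPM with WT replicate 1 at 184, Csf3r 7 and 5.6, camera adjusted p = 0.0356, and adjusted p = 0.587 with an estimated correlation), a call lost without WT replicate 1 or ALAS1/2-KO replicate 1 or 2 (0.0936, 0.0652 and 0.0621) and with that covariate (0.219). Without WT replicate 1 the log2 fold change of gene Lcn2 turned from -0.48 to 0.28 (limma adjusted p = 0.757). Among 3 cholangiocyte markers Spp1 fell (1 adjusted over the list alone). In all, 19 of the 39 lists passed camera with the preset correlation, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 2 by fry. With all libraries kept, the preset-correlation call was also lost under at least 1 other setting for the cholesterol, fatty acid oxidation, p53 and pericentral lists, with adjusted p up to 0.557, 0.259, 0.0953 and 0.0953. With CPM rescaled to listed reads, list medians near 0 turned positive with the median of all genes, while the negative medians of the cell type marker lists with 5 or more tested members remained negative.

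**Figure D3:**
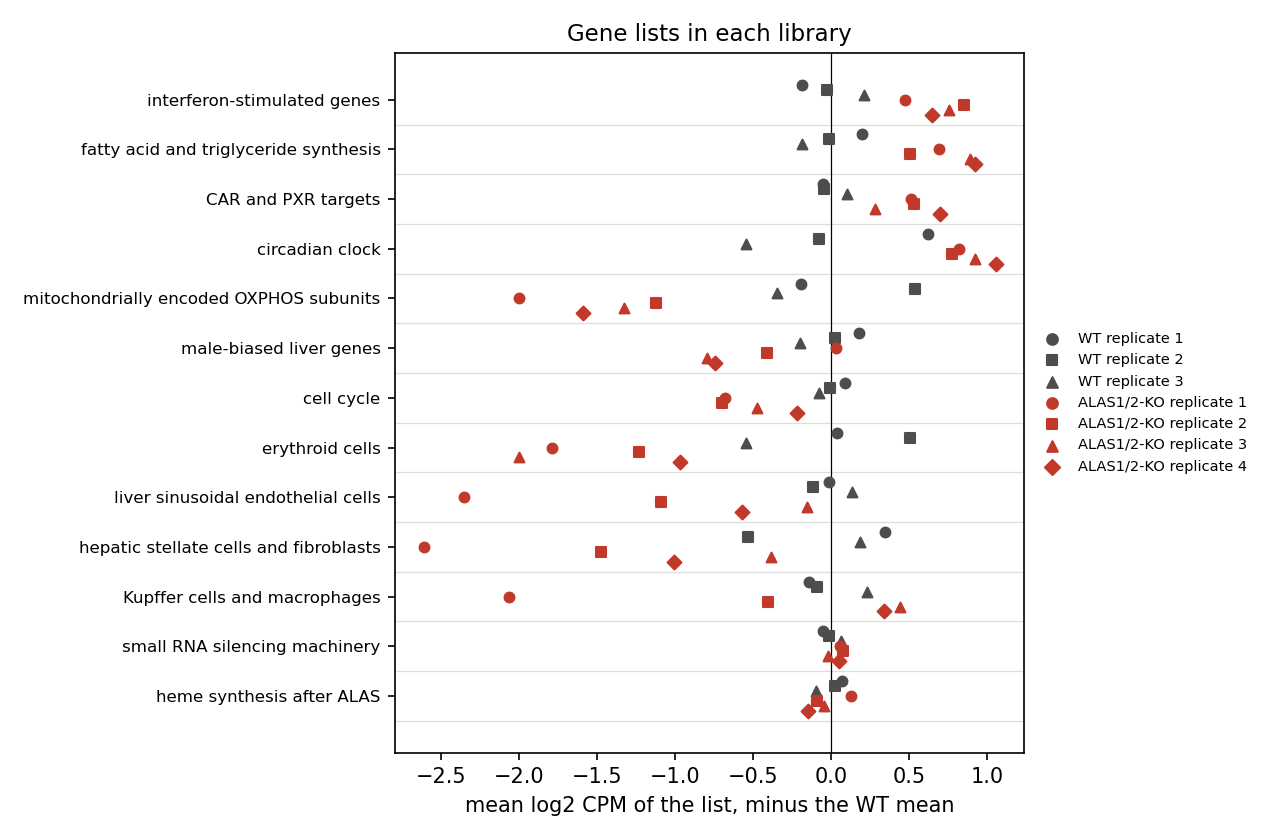
Mean log2 CPM of 13 gene lists in each library, relative to the WT mean, for 3 WT (grey) and 4 ALAS1/2-KO (red) libraries with a marker shape per replicate. Interferon, fatty acid synthesis and clock lists lie to the right in ALAS1/2-KO, and endothelial, stellate and Kupffer markers spread widely there, with replicate 1 lowest at -2.35, -2.61 and -2.07.

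No gene of the small RNA silencing list passed the test. Of 31 components of the machinery 0 were called by limma and by limma voom, with 0 adjusted over the list alone and 7 at an unadjusted p under 0.05, and their median log2 fold change was 0.01 (camera adjusted p = 0.407). The 7 of 31 are close to the share over all genes, 2869 of 12105. By fry's mixed test, which asks for change in either direction, the list had an adjusted p = 0.00498, as 28 of the 39 lists passed that test. Hsp90ab1, a chaperone used in loading Argonaute, stood at 420 and 417 CPM, and Fkbp4, a co-chaperone, at 116 ± 10.8 and 75.2 ± 13.5 CPM (SD, n = 3 and 4, limma adjusted p = 0.0522). Of 19 transcripts listed as targets of miR-122, the most abundant hepatocyte microRNA, Ccng1 rose and 0 fell (1 adjusted over the list alone, camera adjusted p = 0.751, upward with a median of 0.03 against a mean of -0.02). Ccng1 also belongs to the p53 list.

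Genes with 8mer sites for liver microRNAs were not shifted past the threshold. For miR-122-5p, 364 genes with a site differed from matched genes by -0.02 ± 0.02 in WT and 0.02 ± 0.03 in ALAS1/2-KO (mean log2 deviation, SD, n = 3 and 4), a shift of 0.039 (exact p = 0.1429, adjusted p = 0.4286). The let-7-5p family gave 0.057 over 410 genes (exact p = 0.0571), miR-103-3p 0.071 over 428 genes (exact p = 0.0857) and miR-30-5p 0.060 over 929 genes (exact p = 0.1429), each with an adjusted p of 0.4286. Without ALAS1/2-KO replicate 1 the shift of miR-103-3p was 0.043. The control families miR-124-3p, miR-1a-3p and miR-9-5p gave -0.0019, -0.0058 and -0.037. With a library left out they ran from -0.0236 (without ALAS1/2-KO replicate 3) to 0.0224 (without ALAS1/2-KO replicate 1), from -0.0134 (without WT replicate 1) to -0.0008 (without WT replicate 2) and from -0.0488 (without ALAS1/2-KO replicate 3) to -0.0209 (without ALAS1/2-KO replicate 1). By the exact permutation test 0 of 15 families passed, and 0 had an unadjusted p under 0.05. With 8mer or 7mer-m8 sites let-7-5p (0.037), miR-192-5p (0.016) and miR-103-3p (0.026) reached the smallest exact p of 0.0286, with an adjusted p of 0.1429, while miR-122-5p gave 0.022 (exact p = 0.3429). Against unmatched genes miR-122-5p gave 0.023 (exact p = 0.7429). A single shifted family cannot pass this adjustment, so a shift of the size seen here is neither shown nor excluded.

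**Figure D4:**
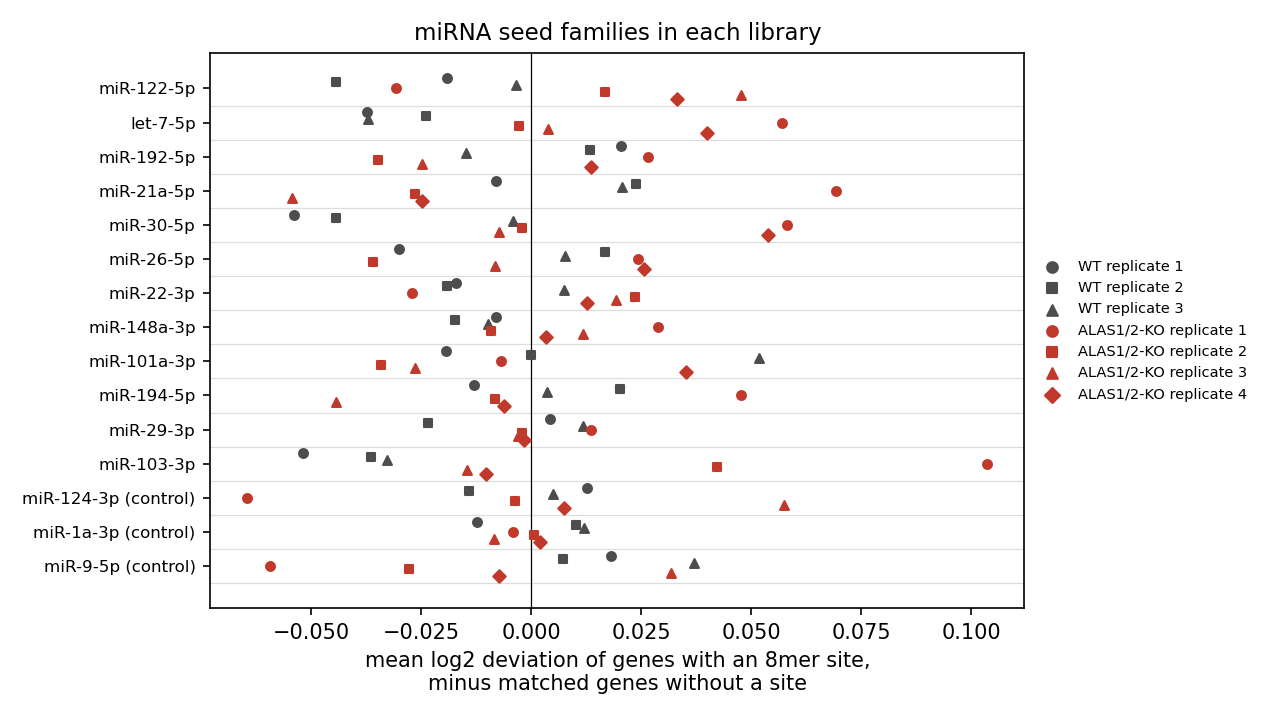
Mean log2 deviation of genes with an 8mer site minus matched genes without a site, for 15 seed families in each library, 3 WT (grey) and 4 ALAS1/2-KO (red), with 3 control families at the bottom. The groups overlap for miR-122-5p and differ by at most 0.071, for miR-103-3p, where replicate 1 of ALAS1/2-KO lies farthest right.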

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

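The tests of explanations here were chosen after the results had been seen. Among 174 values checked in the 4 ALAS1/2-KO libraries, 13 (7.5%) had a library far from the other 3, its gap to the nearest, over the range of the 4, being above Dixon's critical value. Chance gives about 1 in 20, and groups of 3 were not tested. Of the 13, 9 were in ALAS1/2-KO replicate 1.

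In replicate 1, log2 CPM was 9.20 for Ces2a (others 9.51 to 9.52), 8.82 for Ehhadh (8.39 to 8.45), 7.80 for Akr1c6 (7.12 to 7.22), 4.05 for Aen (3.70 to 3.74) and 1.15 for Ighm (2.18 to 2.27). Relative to WT, its list mean was -1.26 for inflammatory cytokines and chemokines (others -0.22 to -0.15), -1.13 for dedifferentiation and regeneration (-0.52 to -0.41) and -2.05 for lymphocytes (-0.50 to -0.25). Its miR-29-3p seed value was 0.014 (-0.003 to -0.002). Replicate 2 stood apart in Creb3l3 (log2 CPM 7.78, others 8.11 to 8.15), in fatty acid oxidation and ketogenesis (-0.44, others 0.22 to 0.31) and in the periportal list (0.53, others 0.14 to 0.20). Replicate 4 stood apart in Tsen54 (2.39, others 1.96 to 1.97).

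Stellate and endothelial markers had lower means in ALAS1/2-KO with 0 single markers called by limma (13 and 6 at an unadjusted p under 0.05, 0 and 1 by limma voom), and replicate 1 was lowest in both lists. On the log2 scale their joint mean, ALAS1/2-KO minus WT, was -1.197 with all libraries (exact p = 0.0857) and -0.771 without replicate 1, where replicate 3 (-0.27) lies within the WT range of -0.31 to 0.16. Replicates 2 (-1.271) and 4 (-0.777) lie below that range, which argues against replicate 1 alone making the difference. Whether the fall without replicate 1 exceeds the spread between libraries cannot be told with 3 libraries left. Stellate minus Kupffer markers, ALAS1/2-KO minus WT, was -0.947 and lower in each ALAS1/2-KO library than in any WT library (exact p = 0.0286). That argues against a like loss of all non-parenchymal cells in replicates 2 and 4 (-1.069 and -1.344). In replicate 3 (-0.828) the stellate mean of -0.386 lay within the WT range of -0.531 to 0.344. Its Kupffer mean of 0.442 lay above each WT library, so its difference shows no stellate loss. For replicate 1 the difference does not argue against a like loss, since its -0.546 lay close to the -0.44 of WT replicate 2. There the stellate, endothelial and Kupffer means all fell (-2.612, -2.352 and -2.065). A different yield of each cell type in the preparations, or a change in the livers, may remain, and the design gives no way to separate them.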

How the results depend on the processing

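The pseudocount of 1, CPM rescaled to listed reads, limma voom, the marker score as covariate and the joint removal of ALAS1/2-KO replicates 1 and 2 were chosen after seeing the data. The counts of genes changed (617), genes higher in ALAS1/2-KO (352) and genes lower in ALAS1/2-KO (265) became 355, 184 and 171 without the limma trend, 2001, 1030 and 971 with array weights, 1130, 565 and 565 without ALAS1/2-KO replicates 1 and 2, and 267, 110 and 157 at a log2 fold change of at least 1. CPM rescaled to listed reads gave 2735 changed and 2533 higher, scaling without the 20 most abundant and mitochondrial genes 221 higher, and the covariate 401 lower. Leaving out a single library gave 100 to 802 changed, 58 to 389 higher and 42 to 413 lower, and 94 of the 617 genes passed in all 7 such fits. Fewer libraries account for part of the smaller counts, and otherwise the cause was not tested. limma voom gave 634 genes, 583 of them among the 617, and a pseudocount of 1 gave 714, with 615 shared. Same-numbered libraries showed no sign of pairing (correlations of their deviations -0.03, 0.05 and 0.18, against -0.33 to 0.36 for other pairs). So few pairs cannot exclude it. With a replicate block 72 genes changed, 33 higher and 39 lower. Without known pairs that count neither shows nor excludes a weaker effect.

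The Alas2 log2 fold change kept its direction and its call in every fit run, at -4.86 to -3.02 with adjusted p of at most 0.0382, and from -4.84 to -4.17 with a library left out. The Alas1 log2 fold change was called only with CPM rescaled to listed reads (1.14). Lists past the threshold (19) numbered 11 with a filter of 5 CPM, under which the erythroid, lymphocyte and neutrophil lists were too small to test, 0 with an estimated correlation and 2 with fry, and 13 to 21 with a library left out. For seed families the count of 0 was close to fixed by the design, which needs at least 9 of 15 at the smallest p and allows none with a library left out, so it says nothing about stability. Direction reversed for Alb (0.28) after quantile normalization, which also took the difference of mt-Nd2 to 0. A reversal was also seen for gene Cd5l (from -0.29 to 0.84 with the covariate, 0.66 without ALAS1/2-KO replicates 1 and 2) and for the Kupffer list (0.57 and 0.37). The covariate is built from the Kupffer, stellate and endothelial lists, so its values for them follow in part from its construction, and otherwise the cause was not tested. Over 2473 values of 113 named genes, 2157 stayed on their side of the threshold, 296 lost and 16 gained a call. Over 932 values of 39 lists, 812 stayed, 91 lost and 27 gained it. Sign changes without a call in either fit numbered 37 for the named genes and 44 for the lists, and count as having stayed. The count tests planned on recovered reads, edgeR and DESeq2, were not run, a choice made because the deposited unit is log2. The recovered reads would have allowed them, and limma voom was run on these reads instead. At this depth 10.2% of simulated changes of 0.5 on the log2 scale were recovered, so changes of that size can be missed. The simulation changed 200 genes and 1 list, fewer than the 617 genes called in the real data, which makes its adjusted threshold stricter. It does not give the share missed in the real data.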

Other observations

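All tests of explanations in this part, and the gene families named here, were chosen after the results had been seen. Several groups of genes that share a symbol stem were enriched among the changed genes, which were 617 of 12105 overall in limma. Fisher's exact test pooled both directions and took genes as independent. Members of a family may move together or share reads, so its p-values may be too small. The mt- stem had 0 of 21 higher and 8 lower (Fisher's exact test, adjusted p = 0.000334). Of 204 stems with at least 8 tested genes, Cyp had 12 of 66 higher and 6 lower (Fisher's exact test, adjusted p = 5.93e-07). Carboxylesterases, which cleave esters of drugs and lipids, had 7 of 12 higher and 0 lower (Fisher's exact test, adjusted p = 5.58e-05). Ces1g rose from 201 ± 5.78 to 497 ± 49.2 CPM and Ces1d from 480 ± 5.98 to 912 ± 205 CPM (SD, n = 3 and 4). Glutathione transferases of the Gstm group had 4 of 8 higher, 1 of them the pseudogene Gstm2-ps1 (adjusted p = 0.0135). Glucuronosyltransferases went both ways, with 2 of 14 higher, Ugt1a1 (126 to 272 CPM) and Ugt1a5, and 4 lower, among them Ugt2b1, Ugt2b36 (573 to 293 CPM) and Ugt2a3 (338 to 141 CPM).

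Major urinary proteins, pheromone carriers made by the liver, had 6 of 19 lower and 0 higher (Fisher's exact test, adjusted p = 0.0107), including Mup3, Mup11 (284 to 126 CPM) and Mup1 (77 to 31.5 CPM). The Ly stem, which holds Ly6 genes and unrelated ones, had 4 of 10 higher and 0 lower (adjusted p = 0.032): Ly6a, Ly6c1, Ly6d and Ly6e, the last from 375 ± 47.2 to 660 ± 83.1 CPM. Members of the Ces, Gstm, Ugt, Mup and Ly6 families resemble each other in sequence, so values of single members are uncertain.

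Other groupings of the 7 libraries into 4 and 3 make 35 splits. In 1 of 35, the real one, as many genes changed (617, highest other 1). The same held for the 352 higher (1 of 35, highest other 1) and the 265 lower (1 of 35, highest other 1). No smaller share than 1 of 35 is possible, and every other split mixes the groups, which widens the spread within them. The counts therefore go with the real grouping, but chance is not excluded. Counts of gene lists past the camera threshold did not single out the real grouping. In 5 of 35 splits as many as 19 lists passed, the highest other being 21.

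Alas2 fell with the hemoglobin transcripts, whose summed log2 CPM was 2.19 lower in ALAS1/2-KO (ALAS1/2-KO minus WT -2.19, exact p = 0.0286). Across WT replicates 1, 2 and 3 the 2 did not follow each other. Alas2 stood at log2 CPM 4.08, 3.37 and 2.75, and summed hemoglobin at 4.43, 5.37 and 3.51. How much Alas2 red cells carry per hemoglobin transcript was not measured here. Fewer red cells in these preparations may account for a part of the Alas2 fall, of unknown size. They do not account for all of it, since the log2 ratio of Alas2 to hemoglobin differed by -2.32 (ALAS1/2-KO minus WT), lower in each library than in any WT library (SD 0.86, n = 3, and 1.01, n = 4, exact p = 0.0286). The siRNA named in the design remains open as a cause, as does a loss of red cell precursors that carry more Alas2 per hemoglobin transcript, which was not tested.

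Some lipogenic genes and some clock genes were higher in ALAS1/2-KO. Genes of the evening phase (10, such as Per2 and Per3) minus genes of the opposite phase (4, such as Arntl and Nfil3) differed by 2.382 on the log2 scale (exact p = 0.0286), with the evening genes 1.63 higher and the opposite genes -0.75, as a later harvest would give, so a different time of day is a candidate explanation. The WT libraries differed in the same contrast (1.499, 0.15 and -1.64 in replicates 1, 2 and 3), and replicate 1, nearest to ALAS1/2-KO, had a fed-state mean of 0.23 against 1.14 to 1.43 in ALAS1/2-KO. Feeding before harvest cannot be told apart, because fasting genes, which a fed state would lower, differed by 0.049. That was above WT but by less than their spread (SD 0.26), with members in both directions. A response to the genotype, tamoxifen or the siRNA stays open and untested. The bound first written, any value at or above WT, would have counted the 0.049 against feeding, and it was widened to the spread after the value was seen.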
